A study of Mus musculus with 4059 samples.

How the data were processed

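Processed fragments of 4059 single cells were analysed, each cell being 1 sample of the series. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie2 2.3.1, Picard and bedtools 2.25.0, with the mouse build mm10. The notes give neither the role nor the settings of each tool. Each deposited table lists aligned read ends with a mapping quality score as its only measured column, and the score as deposited by the authors ran from 31 to 44. Lines came in pairs without exception, both ends of a pair on the same chromosome, with the longest fragment at 2000 bp. Each pair was taken as 1 fragment, and no count, peak or normalised value by the authors was used. Identical fragments within a cell were 0.0288% to 0.0657% of a group's fragments and were kept. The notes do not say whether repeats had been removed before.

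Groups follow the labels for antibody, organ and stage. The labels name no animal, litter or batch, so each of the 10 groups was 1 sample, cells were summed within it, and no p-value, standard error or count of changed genes was computed. Read names showed sets of sequencing lanes, which were treated as batches. E16.5, P5 and adult heart cells lay in the same 2 sets, all aged cells in another, ERG in 4 sets and TWIST1 in 3, so that aged against adult and ERG against TWIST1 have no set in common.

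Gene spans came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, with 21631 protein-coding genes used. Fragment midpoints within a single gene on chromosomes 1 to 19 and X were summed per group and divided by the group's total of such fragments. Ratios had 0.5 added to each sum and an exact conditional binomial 95% interval. Shares have exact (Clopper-Pearson) binomial intervals and sums exact Poisson intervals, and all cover counting error only.

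Before the data were examined, the groups, the comparisons, 33 gene lists, the rule for named genes and most alternatives were fixed. The lists were 20 sets of cell type markers and 13 sets of pathway genes. Of 515 list genes, 513 were found in the table, and H19 and Meg3, which are non-coding, were not. A list's value is the median log2 ratio over members with at least 20 fragments in the groups compared, with an interval from 1000 Poisson redraws of the counts and a percentile among 10000 random lists of equal size matched on deciles of mean level. Named genes are, per heart comparison, the 12 highest and 12 lowest autosomal genes with at least 100 fragments, ranked by the bound of the interval nearest to no difference. Per organ they are the 5 genes highest over the highest other organ, and at gene ends the 12 highest for each factor with at least 30 fragments. Of each list described, members are taken from the 4 with the most fragments, Cdh5, Erg and Twist1 are always given, and predicted genes named Gm or Rik were left out. Some genes that these rules pick are not reported here.

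The gene table gives no strand, so the planned windows at transcription starts became windows at both gene ends. For the same reason, the alternative without the start of a gene left out 2 kb at both ends of genes over 8 kb. No genome was used, so the planned motif densities and their alternatives were not run. For clusters, gene-body counts of H3K36me3 cells with at least 1000 fragments, over genes seen in at least 1% of cells, were weighted by term frequency and inverse document frequency. They were reduced to 30 components, leaving out those whose correlation with log depth exceeded 0.5, and clustered by Leiden at resolution 1 on 15 nearest neighbours.

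Alternatives changed the scaling, repeats, gene region, cells, depth, background, minimum count and cluster settings. Those chosen after the data were seen were each set of lanes alone, repeats within a set of lanes, whole gene bodies and the ribosomal DNA segment for ERG and TWIST1, clusters without list genes, and leaving out the deepest 5% of cells.

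The steps were tested on simulated data. Counts for the ratios were drawn as Poisson counts, without spread between animals, cells or sets of lanes, so the shares below check the steps only. For adult against P5, over 3935 genes, the interval held the true ratio for 95.6% of unchanged genes. It lay on the right side for 100% of genes 2-fold up and 92% of genes 2-fold down, and for 72% and 54% at 1.5-fold. For aged against adult, over 1185 genes, these shares were 98% and 90% at 2-fold and 78% and 52% at 1.5-fold. In 446 simulated cells of 2 populations that differed 3-fold in 200 genes, 5 clusters came out, with 95.1% of cells in clusters of their own population. Without any difference 12 clusters came out. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.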

Results

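Single cells of the Cdh5-positive (endothelial) lineage from C57BL/6 mice were profiled by CoBATCH, in which a transposase carried by an antibody tags chromatin in individually barcoded cells. H3K36me3, a histone mark laid down over the bodies of transcribed genes, was measured in methanol-fixed cells of the heart before birth (E16.5, 709 cells), at postnatal day 5 (P5, 1172 cells), in the adult (396 cells) and in aged mice of 17 to 19 months (249 cells). Aged brain (198 cells), kidney (118 cells), liver (347 cells) and lung (84 cells) were profiled for the same mark. The transcription factors ERG (457 cells) and TWIST1 (329 cells) were mapped in formaldehyde-fixed P5 heart cells. The 4059 cells held 6028049 fragments, with 489 to 17970 per cell and group medians from 796 in aged kidney to 1426 for TWIST1. Summed per group, the fragments numbered 815430 at E16.5, 1303733 at P5, 554621 in the adult heart, 282081 in the aged heart, 358185 in brain, 152811 in kidney, 516108 in liver, 114326 in lung, 1090813 for ERG and 839941 for TWIST1. No animal is named for any cell, so each group counted as 1 sample, there were no replicates and no test between groups was possible. Every interval below is a 95% interval of counting error only.

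H3K36me3 fragments lay mostly in genes. Protein-coding gene bodies, which cover 39.5% of the genome, held 72.4% of the H3K36me3 fragments at E16.5, 75.8% at P5, 70.4% in the adult heart and 73.6% in the aged heart. In the aged organs the share was 72.3% in brain, 74.3% in kidney, 75.0% in liver and 75.0% in lung. ERG and TWIST1 fragments were less concentrated there, at 57.9% and 59.7%.

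The first comparison asks how the mark on gene bodies differed between the heart before and after birth. The general and the heart endothelial lists carried slightly more H3K36me3 at P5 than at E16.5, and neural, cardiomyocyte and some other cell type lists carried less. Gene bodies also held a larger share of fragments at P5 (75.8%) than at E16.5 (72.4%). A different share of fragments not targeted by the antibody could shift such lists together, which was not tested for this comparison. The median log2 ratio of the endothelial list was 0.19 (0.07 to 0.32), with 21 of 31 measured members higher, among them Eng, a TGF-beta co-receptor, at 1.39 (1.19 to 1.64) times the E16.5 level, and the adhesion receptor Pecam1 at 1.26 (1.08 to 1.48) times. Genes of heart capillary endothelium were higher by 0.50 (0.14 to 0.89), with 7 of 9 members higher and Rgcc at 2.45 (1.44 to 4.63) times. Fatty acid use genes were higher by 0.37 (0.04 to 0.47), and Mgll, which releases fatty acids from monoglycerides, stood at 1.54 (1.31 to 1.83) times. Neural genes were lower, at -0.67 (-0.92 to -0.47), 11 of 11 members lower, with the neuronal splicing factor Rbfox3 at 0.617 (0.530 to 0.718) times, and cardiomyocyte genes at -0.45 (-0.67 to -0.23), 16 of 18 members.

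Among the other lists, the angiogenesis median was 0.20 (0.06 to 0.31) with 15 of 18 members higher, and the Notch median 0.25 (0.05 to 0.38). Genes of ETS factors, the family of ERG, had a median of 0.18 (0.05 to 0.36). NF-kB and adhesion genes were at 0.14 (0.01 to 0.43). Not every vascular list was higher: liver sinusoidal genes were lower, at -0.57 (-0.83 to -0.19), 8 of 8 members lower, and lymphatic genes at -0.38 (-0.64 to -0.03), while brain endothelial genes were at -0.23 (-0.48 to 0.07). Lymphocyte genes were lower, at -0.59 (-0.78 to -0.23), kidney epithelial genes at -0.64 (-1.01 to -0.23), mural cell genes at -0.47 (-0.79 to -0.12), hepatocyte genes at -0.57 (-0.91 to -0.09) and erythroid genes at -0.33 (-0.63 to -0.09). Fibroblast genes, at -0.34 (-0.57 to 0.24), myeloid genes, at -0.21 (-0.53 to 0.0065), and lung epithelial genes, at -0.23 (-0.60 to 0.03), had intervals that held 0. Of the 33 lists, 8 had an interval above 0, 9 an interval below 0 and 16 an interval that held 0. Cell cycle genes had a median of 0.15 (0.02 to 0.31), which was 0.014 when the 2 kb at each gene end were left out. Within the first and the second set of sequencing lanes, the endothelial median was 0.36 and 0.20, the heart endothelial median 0.39 and 0.86, the neural median -0.56 and -0.81, and the cardiomyocyte median -0.36 and -0.32 (-0.68 to 0.05), an interval that held 0. So did those of lymphocyte -0.37 (-0.70 to 0.09), kidney epithelial -0.40 (-1.53 to 0.45), mural -0.42 (-0.81 to 0.18), hepatocyte -0.37 (-1.02 to 0.42), erythroid -0.36 (-0.70 to 0.21), liver sinusoidal -0.31 (-0.71 to 0.14) and NF-kB genes 0.24 (-0.07 to 0.55) in the second set, and of lymphatic genes in both, at -0.36 (-0.65 to 0.10) and -0.15 (-0.54 to 0.17). The cell cycle median was 0.04 (-0.12 to 0.27) in the first set and 0.42 in the second. The angiogenesis median was 0.26 in the first set and 0.020 (-0.19 to 0.21) in the second, so it did not hold in both. Fatty acid use medians were 0.33 and 0.36 and Notch medians 0.22 and 0.18, with intervals that held 0 in each set. Against random lists of genes with similar fragment numbers, the angiogenesis (percentile 97.3), cell cycle (95.2), ETS factor (91.8), NF-kB (77.7), erythroid (6.11), lymphatic (3.07) and hepatocyte (2.99) medians lay inside the 95% range.

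Of single genes, the splicing factor Nova2 (chromosome 7, 18925888 to 18965319) was higher at P5 by 2.21-fold (1.65 to 3.06), with 205 against 55 fragments. The chromatin reader Brd2 was higher by 2.20-fold (1.52 to 3.32), the translation helicase Eif4a1 by 2.17-fold (1.44 to 3.47) and the Hedgehog receptor Ptch1 by 1.88-fold (1.42 to 2.54). Strn, Ube2d3, Fig4, Gpbp1l1, N4bp3, Sbno1, Cdk2ap1 and Zc3h10, were 1.80-fold (N4bp3) to 2.27-fold (Ube2d3) higher. Chadl was lower at P5 by 2.76-fold (1.83 to 4.26) and the heart muscle formin Fhod3 by 2.33-fold (1.62 to 3.39). Runx3 was lower by 2.03-fold (1.55 to 2.66), and Otof, Zfp469, Elfn2, Slc4a11, Slit1, Ephb2, Wnt9a and Rab11fip4 by 1.85-fold (Zfp469) to 2.28-fold (Slc4a11). The lineage gene Cdh5 was lower at P5 by 1.58-fold (1.29 to 1.94), and Erg was at 1.14-fold (0.910 to 1.44) of its E16.5 level. Twist1 held 3 fragments at P5 and 4 at E16.5, too few for a comparison. Values at Cdh5 have a limit of their own, since a segment of 170 kb around it held more fragments than the genome mean. The excess was 4.56 times (H3K36me3 at P5) to 10.8 times (TWIST1) in the E16.5, P5, adult, ERG and TWIST1 libraries. In the aged libraries it was smaller, from 1.4 times in kidney to 2.05 times in liver. Intervals held 1 in aged kidney (1.4 times, 0.768 to 2.36) and lung (1.74 times, 0.928 to 2.98).

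The second comparison sets the adult heart against P5. Endothelial and cell cycle genes carried less H3K36me3 in the adult library, and genes of heart muscle, neurons and several other cell types carried more. Gene bodies held 70.4% of adult fragments against 75.8% at P5, and untargeted fragments are weighed below only for lists that were higher. The endothelial list was lower, with a median log2 of -0.58 (-0.73 to -0.43), 29 of 32 members lower, with Pecam1 at 0.570 (0.460 to 0.696) times, Flt1, a VEGF receptor, at 0.657 (0.549 to 0.779) times and Eng at 0.625 (0.510 to 0.757) times the P5 level. Cell cycle genes were lower, at -0.68 (-0.95 to -0.45), 36 of 41 members lower, with the DNA methylation maintenance factor Uhrf1 at 0.408 (0.272 to 0.581) times, while Dnmt1 stood at 1.08 (0.875 to 1.32) times. The cardiomyocyte list was higher by 1.07 (0.85 to 1.30) and the neural list by 1.03 (0.74 to 1.24), in 19 of 19 and 12 of 12 members. The cardiac calcium channel Cacna1c stood at 2.21 (1.77 to 2.76) times and Rbfox3 at 2.08 (1.77 to 2.43) times.

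Of the 33 lists, 12 had an interval below 0. Besides those above, these were the ETS factors at -0.59 (-0.82 to -0.44), 12 of 12 members lower with Elk3 at 0.520 (0.393 to 0.672) times, heart endothelial genes at -0.59 (-1.13 to -0.18), extracellular matrix at -0.33 (-0.58 to -0.21), Notch at -0.46 (-0.63 to -0.25), angiogenesis at -0.33 (-0.59 to -0.20), fetal growth at -0.46 (-0.76 to -0.20), oxidative phosphorylation at -0.26 (-0.59 to -0.09), NF-kB and adhesion at -0.40 (-0.63 to -0.15), senescence at -0.43 (-0.74 to -0.07) and endothelial-to-mesenchymal transition at -0.16 (-0.50 to -0.01). Another 10 had an interval above 0: besides the cardiomyocyte and neural lists, kidney epithelial at 0.86 (0.27 to 1.18), hepatocyte at 0.82 (0.16 to 1.20), kidney endothelial at 0.70 (0.18 to 0.92), erythroid at 0.61 (0.23 to 0.97), lymphocyte at 0.58 (0.24 to 1.05), myeloid at 0.58 (0.09 to 0.87), fibroblast at 0.49 (0.24 to 0.95) and mural at 0.38 (0.01 to 0.66). The remaining 11 held 0: endocardial 0.10 (-0.53 to 0.50), brain endothelial 0.20 (-0.21 to 0.55), liver sinusoidal -0.08 (-0.45 to 0.24), lung endothelial -0.15 (-0.51 to 0.18), lymphatic 0.00 (-0.44 to 0.38), arterial -0.05 (-0.40 to 0.20), venous 0.07 (-0.57 to 0.51), lung epithelial 0.29 (-0.32 to 0.58), fatty acid use -0.20 (-0.40 to 0.12), glycolysis -0.18 (-0.37 to 0.02) and interferon and antigen presentation -0.05 (-0.17 to 0.39). Among random lists of genes with similar fragment numbers, 10 of these medians with intervals off 0 lay inside the 95% range, so they did not stand apart from other genes. These were endothelial-to-mesenchymal transition (percentile 30.9), oxidative phosphorylation (12.3), NF-kB and adhesion (7.85), senescence (6.34), angiogenesis (5.74), heart endothelial (3.89), matrix (3.34), mural (89.9), fibroblast (94.1) and erythroid genes (96.8).

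**Figure D1:**
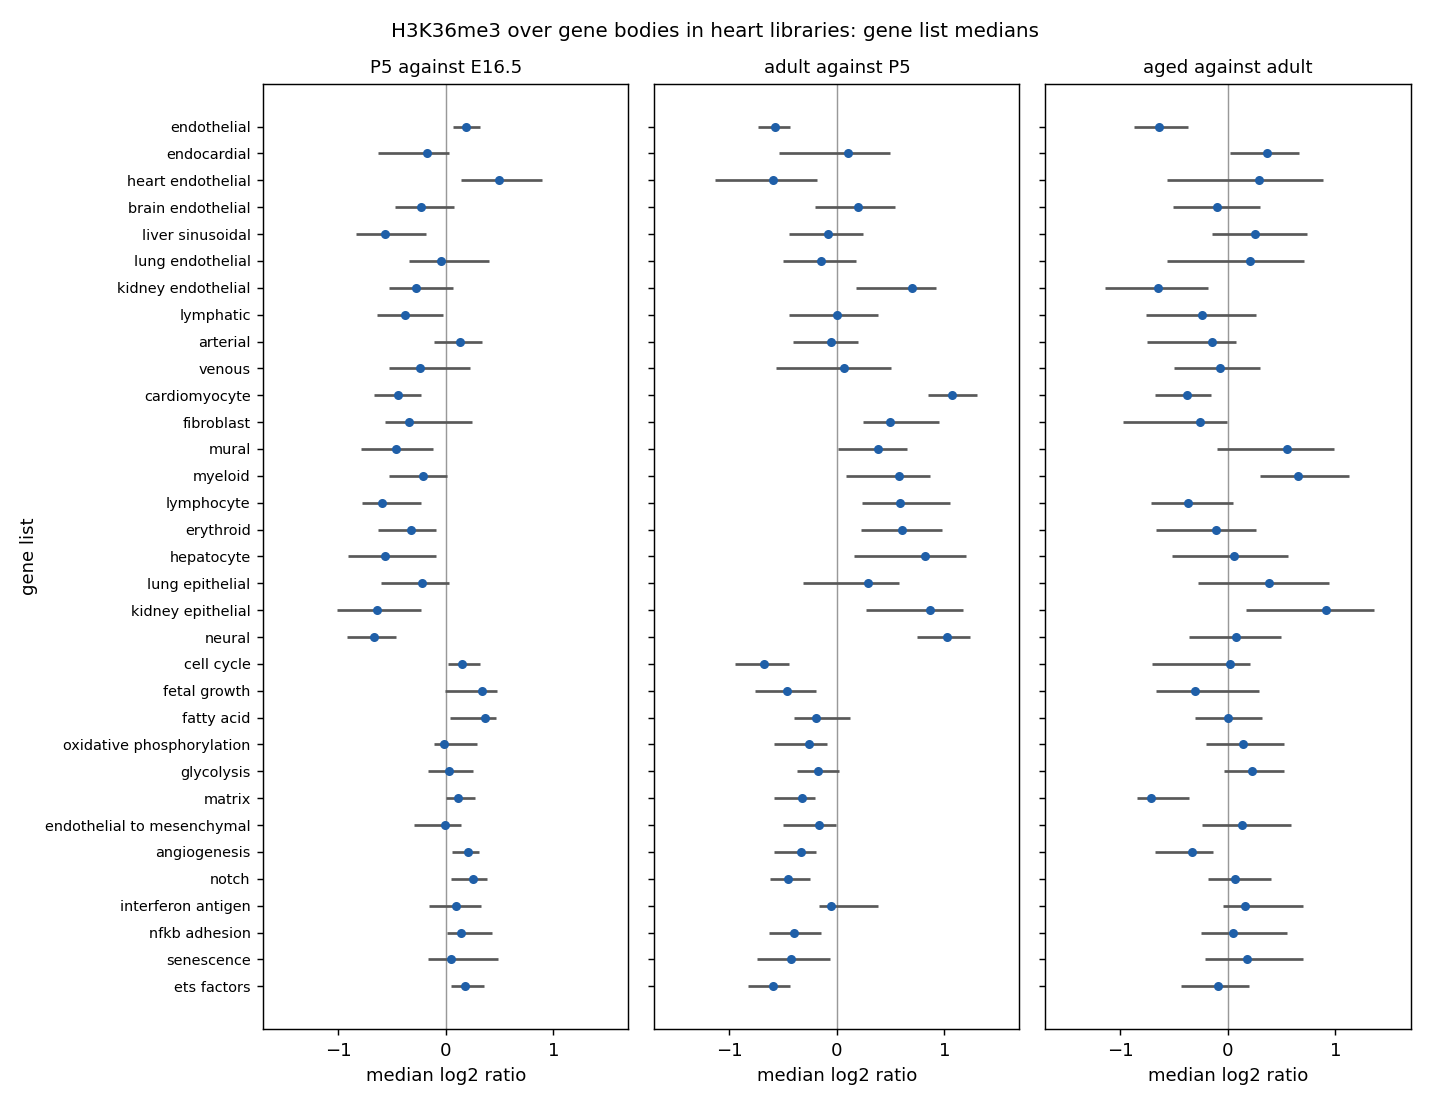
Median log2 ratio of H3K36me3 over gene bodies (horizontal axis) for each of the 33 gene lists (vertical axis) in the 3 heart comparisons, with bars for 95% intervals. The endothelial median lies at 0.19 at P5 against E16.5, -0.58 in the adult against P5 and -0.64 in the aged against the adult heart.

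Both sets of lanes held adult and P5 cells. Within the first and the second, the endothelial median was -0.56 and -0.56, the cell cycle median -0.67 and -0.67, the cardiomyocyte median 1.17 and 0.99, the neural median 1.10 and 0.79, the ETS factor median -0.46 and -0.77, and the matrix median -0.48 and -0.18. The kidney endothelial median was -0.066 in the first set alone and the fetal growth median 0.029 in the second, and kidney epithelial genes were at -0.52 in even-numbered cells, over 2 members. Intervals also held 0 in the first set for heart endothelial -0.35 (-1.19 to 0.09), kidney epithelial 0.35 (-0.17 to 1.11), senescence -0.40 (-0.75 to 0.12) and oxidative phosphorylation genes (-0.084, -0.63 to 0.13), in the second for fibroblast 0.53 (-0.03 to 0.98), mural 0.21 (-0.13 to 0.85) and hepatocyte genes (1.0, -0.05 to 1.47), and in both for myeloid genes, at 0.21 (-0.17 to 0.78) and 0.56 (-0.07 to 0.95), and endothelial-to-mesenchymal transition, at -0.19 (-0.59 to 0.04) and -0.06 (-0.68 to 0.14). The median of all genes was -0.066, and -0.17 when scaled to all fragments. With the density between genes subtracted, the cell cycle median was -1.27.

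Of single genes, Tmem132c (chromosome 5, 127241826 to 127565790) was higher in the adult library by 5.72-fold (3.76 to 9.03), the myosin heavy chain gene Myh14 by 4.44-fold (3.08 to 6.53), Igsf21 by 3.84-fold (3.02 to 4.92) and Abcc8, a subunit of potassium channels, by 4.19-fold (2.79 to 6.43). Grid1, Wscd2, Ntng2, Igsf9b, Crtac1, Tafa5 and Cdh4 were 3.11-fold (Cdh4) to 3.93-fold (Wscd2) higher. The apoptosome gene Apaf1 was lower by 3.83-fold (2.23 to 7.63), Rasip1, which is needed for vessel lumens, by 3.19-fold (2.19 to 4.93) and the transcription factor Tcf4 by 2.51-fold (2.03 to 3.17). The basement membrane collagens Col4a1 and Col4a2, neighbours on chromosome 8, were lower by 2.15-fold (1.78 to 2.64) and 2.06-fold (1.79 to 2.39), the latter with 222 against 1158 fragments. Dbn1, Meox1, Dapk3, Kansl2, Rhoc, Rbpms and Atad2 were lower by 2.19-fold (Rbpms) to 3.13-fold (Meox1). Cdh5 stood at 1.06-fold (0.809 to 1.37) and Erg at 0.850-fold (0.644 to 1.10) of the P5 level, both intervals holding 1, and Twist1 held 1 and 3 fragments.

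The third comparison sets the aged heart against the adult heart. The aged library carried less H3K36me3 over endothelial and matrix genes and more over genes of myeloid cells. The endothelial median was -0.64 (-0.87 to -0.37), 18 of 22 members lower, with Pecam1 at 0.655 (0.441 to 0.937) times, Flt1 at 0.639 (0.461 to 0.865) times and Eng at 0.902 (0.653 to 1.22) times the adult level. The matrix median was -0.72 (-0.85 to -0.36), 18 of 19 members lower, with Col4a1 at 0.495 (0.321 to 0.728) times and Col4a2 at 0.715 (0.547 to 0.920) times, and the angiogenesis median -0.33 (-0.68 to -0.14). The myeloid median was 0.66 (0.30 to 1.12), 8 of 11 members higher, with the macrophage growth factor receptor Csf1r at 2.96 (1.57 to 5.85) times and the blood cell transcription factor Runx1 at 2.15 (1.54 to 3.0) times.

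The cardiomyocyte median was -0.38 (-0.68 to -0.16), the kidney endothelial median -0.65 (-1.15 to -0.18), the fibroblast median -0.26 (-0.98 to -0.01) and the kidney epithelial median 0.91 (0.17 to 1.36). Endocardial genes had a median of 0.36 (0.02 to 0.66) over 2 members. The endocardial (percentile 81.4), kidney endothelial (3.55) and fibroblast (13.7) medians lay inside the 95% range of random lists. Senescence genes had a median of 0.18 (-0.22 to 0.70) and interferon and antigen presentation genes 0.16 (-0.04 to 0.70), so neither was detectably different at this depth. Of the 33 lists, 3 had an interval above 0, 6 an interval below 0 and 24 an interval that held 0. The myeloid median turned to -0.051 when members needed 50 fragments, which left 3 members, and the endothelial median was -0.33 in cells with at least 1000 fragments. No set of lanes held both adult and aged cells, so age and set of lanes cannot be told apart, and scaling by the median ratio moved the median of all genes from 0.0078 to -0.15.

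The blood cell gene Arhgap45 (chromosome 10, 80016672 to 80031471) was higher in the aged library by 4.25-fold (2.92 to 6.38), with 91 against 40 fragments. The adenylyl cyclase Adcy7 was higher by 2.67-fold (1.97 to 3.65), the leukocyte phospholipase Plcg2 by 2.48-fold (1.75 to 3.55) and Runx3 by 2.07-fold (1.56 to 2.76). Kif21b, Arap1, Sipa1, Prex1, Lrp1, Pik3r5, Iffo1 and Map3k14 were 1.97-fold (Prex1) to 2.78-fold (Kif21b) higher. The secreted protease Adamts9 was lower by 5.62-fold (2.99 to 13.3), and the receptor phosphatases Ptprm and Ptprg by 3.01-fold (2.11 to 4.52) and 3.22-fold (2.06 to 5.49). Myo10, Dnah8, Plxna4, Ablim1, Kif13a, Dysf, Syne2 and Syn3 were lower by 1.87-fold (Dysf) to 2.44-fold (Dnah8). Cdh5 was lower by 3.59-fold (2.02 to 7.48), with 12 against 84 fragments. The segment of 170 kb around Cdh5 fell as well, from 5.98 times the genome mean in the adult to 1.96 times in the aged heart. Erg stood at 0.775-fold (0.489 to 1.18) of the adult level. Twist1 held 1 fragment in each.

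The aged organs ask whether the mark separates vascular beds of different organs, all 5 in the same set of lanes. Each organ is set against the mean of the others. Liver carried more of the mark over genes of its own vessels: sinusoidal endothelial genes had a median log2 of 0.47 (0.13 to 0.83), 8 of 9 members higher, with the scavenger receptors Stab2 at 1.59 times and Stab1 at 1.28 times, and the transcription factor Gata4 at 2.62 times. Brain endothelial genes in brain had a median of 0.33 (0.04 to 0.62), with Spock2 at 1.46 times and Lef1, a Wnt effector, at 1.35 times, but the sign turned with odd-numbered cells (-0.038) and with groups thinned to the same number of fragments (-0.16). The heart list in heart (0.55, -0.28 to 0.98), the lung list in lung (-0.51, -1.32 to 0.36) and the kidney list in kidney (-0.35, -1.19 to 0.18) had intervals that held 0. The kidney value was 0.31 with equal weight per cell.

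General endothelial genes were higher in heart (0.35, 0.04 to 0.50, and -0.049 in odd-numbered cells) and liver (0.28, 0.08 to 0.43), not detectably different in brain (0.27, -0.02 to 0.43), and lower in kidney (-0.50, -0.88 to -0.18) and lung (-0.47, -1.22 to -0.31). In lung, Shank3 stood at 0.425 times and Eng at 0.529 times the mean of the others. Lymphocyte genes were higher in kidney (0.61, 0.10 to 0.86) and lower in heart (-0.50, -0.90 to -0.25), arterial genes lower in kidney (-0.91, -1.97 to -0.19), neural genes lower in liver (-0.54, -0.80 to -0.17), and cell cycle genes lower in brain (-0.46, -0.71 to -0.11). In brain, oxidative phosphorylation genes (-0.48, -0.68 to -0.01) and NF-kB and adhesion genes (-0.50, -1.02 to -0.20) were lower, but in odd-numbered cells these medians were 0.23 and 0.011. Of the 33 lists, 2 had an interval above 0 and 2 below in heart, 2 and 5 in brain, 1 and 3 in kidney, 2 and 5 in liver, and 0 and 4 in lung. Those not yet named were senescence (0.45, 0.01 to 0.73) and erythroid (-0.49, -0.95 to -0.02) in heart, cardiomyocyte (0.38, 0.02 to 0.53), interferon and antigen (-0.36, -0.73 to -0.18) and glycolysis (-0.26, -0.50 to -0.04) in brain, and angiogenesis (-0.33, -0.67 to -0.08) in kidney. In liver they were fibroblast (-0.62, -0.98 to -0.09), brain endothelial (-0.28, -0.61 to -0.05), matrix (-0.27, -0.45 to -0.01) and cardiomyocyte (-0.22, -0.51 to -0.03), and in lung liver sinusoidal (-0.53, -1.60 to -0.12), Notch (-0.33, -0.88 to -0.10) and matrix (-0.29, -0.80 to -0.04). Of these, glycolysis in brain (percentile 10.5), angiogenesis in kidney (2.86), brain endothelial (5.22), matrix (3.49) and cardiomyocyte (7.69) in liver, and liver sinusoidal (8.02) and Notch (3.24) in lung lay inside the 95% range of random lists. Scaling by the median ratio moved the median of all genes from -0.0087 to -0.24 in lung and from -0.064 to 0.054 in brain, and lung with its 84 cells held the fewest fragments.

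**Figure D2:**
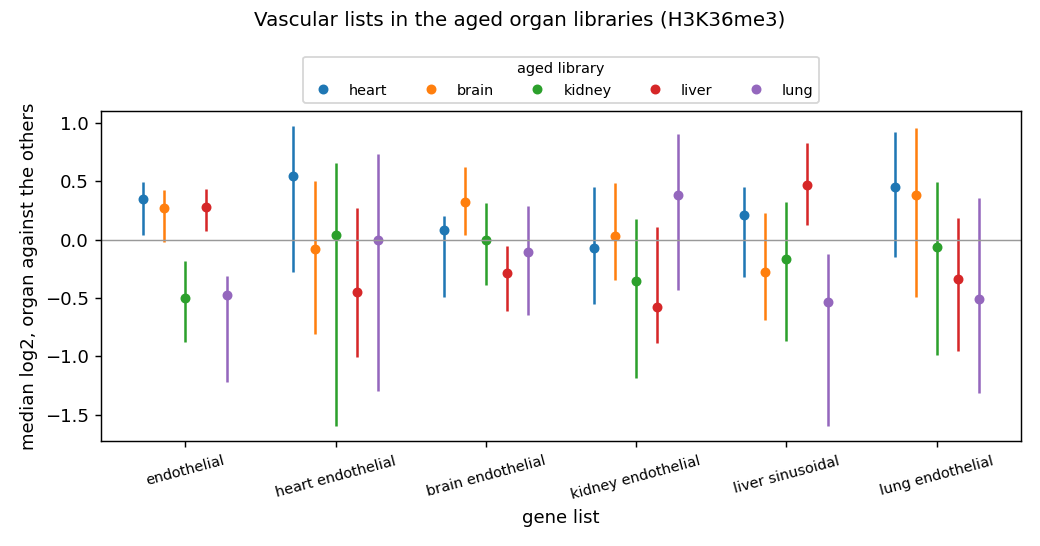
Median log2 of H3K36me3 over 6 vascular gene lists (horizontal axis) in each aged organ against the mean of the other organs (vertical axis), with bars for 95% intervals. The liver point stands at 0.47 for liver sinusoidal genes and the brain point at 0.33 for brain endothelial genes.

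Against the highest other organ, the receptor phosphatase Ptprm was higher in brain by 2.00-fold (1.43 to 2.80), followed by Adgrg1 at 1.63-fold (1.21 to 2.21), Cxxc5, Nectin1 and Nfix. In liver the prostaglandin transporter Slco2a1 was higher by 1.99-fold (1.25 to 3.40), followed by the integrin Itga9 at 1.44-fold (1.13 to 1.85), Capn5, Unc5a and the HDL receptor Scarb1. Heart was led by Fblim1 at 1.71-fold (1.16 to 2.51), then Pdzd2, Plxna1, Daglb and Pald1, the last at 1.34-fold (1.0 to 1.79) with a log2 of -0.089 after thinning. Kidney was led by Aldh3b1 at 1.80-fold (1.20 to 2.64), then Atp2a3, Sun2, Grk3 and Git1, and lung by the polarity gene Scrib at 1.73-fold (1.15 to 2.57), then Sbno2, Itpk1, Abcg1 and Ttc7.

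The last comparison sets ERG, an ETS factor of endothelial cells, beside TWIST1, a basic helix-loop-helix factor of mesenchymal programmes, in P5 heart. Windows of 1 kb around both ends of protein-coding genes, which cover 3.01% of the genome, held 12.8% (12.7 to 12.9) of ERG and 15.5% (15.5 to 15.6) of TWIST1 fragments. H3K36me3 at P5 had 24.6% there, after another fixation. Within sets of lanes the ERG share was 23.2%, 8.62%, 12.9% and 13.0%, and the TWIST1 share 15.1%, 17.8% and 14.8%, so the difference between the factors did not hold across sets. No set of lanes held both factors, and factor and set cannot be told apart.

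Bins of 500 bp with at least 5 fragments numbered 28349 for ERG and 25406 for TWIST1. They shared 6806, which is 24.0% of the ERG and 26.8% of the TWIST1 bins, against 138 if both were spread independently over all bins. No control library was among the groups, so sharing does not show that both factors bind there. Of the shared bins, 40.3% (39.1 to 41.5) lay near a gene end, against 23.2% of bins of ERG alone and 24.9% of bins of TWIST1 alone. Shared bins need at least 5 fragments of each factor, so these shares are not like for like. The bins with the most fragments were the same kind for both: a ribosomal DNA segment on chromosome 17 (39843001 to 39849000), which holds the pseudogene Rn18s-rs5 and took 0.312% of ERG and 0.758% of TWIST1 fragments. With the bins fullest in H3K36me3 at P5 left out, the fullest outside that segment were a bin in the gene Sfi1 (chromosome 11, 3193001 to 3193500), with 219 ERG and 273 TWIST1 fragments, and a bin in the long non-coding RNA gene Gm36876 (chromosome 11, 109011501 to 109012000), with 103 and 194. H3K36me3 at P5 held 28 and 29 fragments there too. No other regions were left out, so these counts alone do not show binding by either factor.

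At gene ends (2 kb to each side), the median log2 ratio of ERG to TWIST1 over 10247 genes was -0.28, and the lists are read relative to it. Endothelial genes were not apart from other genes, with a median of -0.38 (-0.78 to -0.05), at percentile 32.2 of random lists. Glycolysis genes had a median of -0.78 (-1.35 to -0.31) over 9 members, an interval below the median of all genes. At percentile 2.46, this median lay on the lower edge of the 95% range of random lists. None of the lists at gene ends was compared by set of lanes. Genes of endothelial-to-mesenchymal transition had -0.69 (-1.05 to -0.15), at percentile 2.91, and were not apart either, since the interval held -0.28 and the median lay inside the 95% range of random lists. Fatty acid use genes had a median of 0.30 (-0.32 to 0.56), at percentile 99.8, above that range, though the interval held -0.28.

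The ends of Ppargc1a, a coactivator of mitochondrial metabolism, held more ERG by 3.37-fold (1.46 to 10.6), those of the peroxisomal protease Lonp2 by 3.37-fold (1.46 to 10.6) and those of the homeobox gene Meis3 by 2.93-fold (1.39 to 7.71). Zfp281, Fam83f, Tff1, Lhx4, Cpz, Rgp1, Yrdc, Tmem63c and Olfr524 followed. Over its whole body Olfr524 had a log2 of -0.38, the value that equal fragment counts of both factors give at these library sizes. TWIST1 was higher at the mitochondrial sirtuin Sirt4 by 7.04-fold (3.30 to 19.7), at Eapp by 7.22-fold (3.0 to 25.8), at the forkhead gene Foxd2 by 6.75-fold (2.78 to 24.2) and at Tnfaip3, an inhibitor of NF-kB, by 5.51-fold (2.37 to 17.4). Slc26a1, Dusp9 on the X chromosome, Glis2, Grin3b, Bin1, Tsen34, Cramp1l and Mypop followed. Not all of these held by set of lanes. Every ERG set lay above every TWIST1 set at Lonp2, Olfr524 and Fam83f, and the reverse held at Foxd2, Slc26a1, Dusp9, Tnfaip3, Bin1, Tsen34 and Cramp1l. All these ends were picked as extremes of the same fragments, so such agreement is partly fixed by the choice and is no replication. Counts were small, such as 28 ERG and 6 TWIST1 fragments at Lonp2, and extremes picked from many genes can arise from counting error. At the other named ends the sets overlapped, and at Ppargc1a, scaled to library size, the ERG sets held 56.4, 3.33, 57.2 and 24.0 and the TWIST1 sets 5.54, 11.4 and 6.69. At the factors' own genes, Erg held 13 ERG and 10 TWIST1 fragments and Twist1 held 12 and 22. Cdh5 held 103 and 146, within the segment described above.

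**Figure D3:**
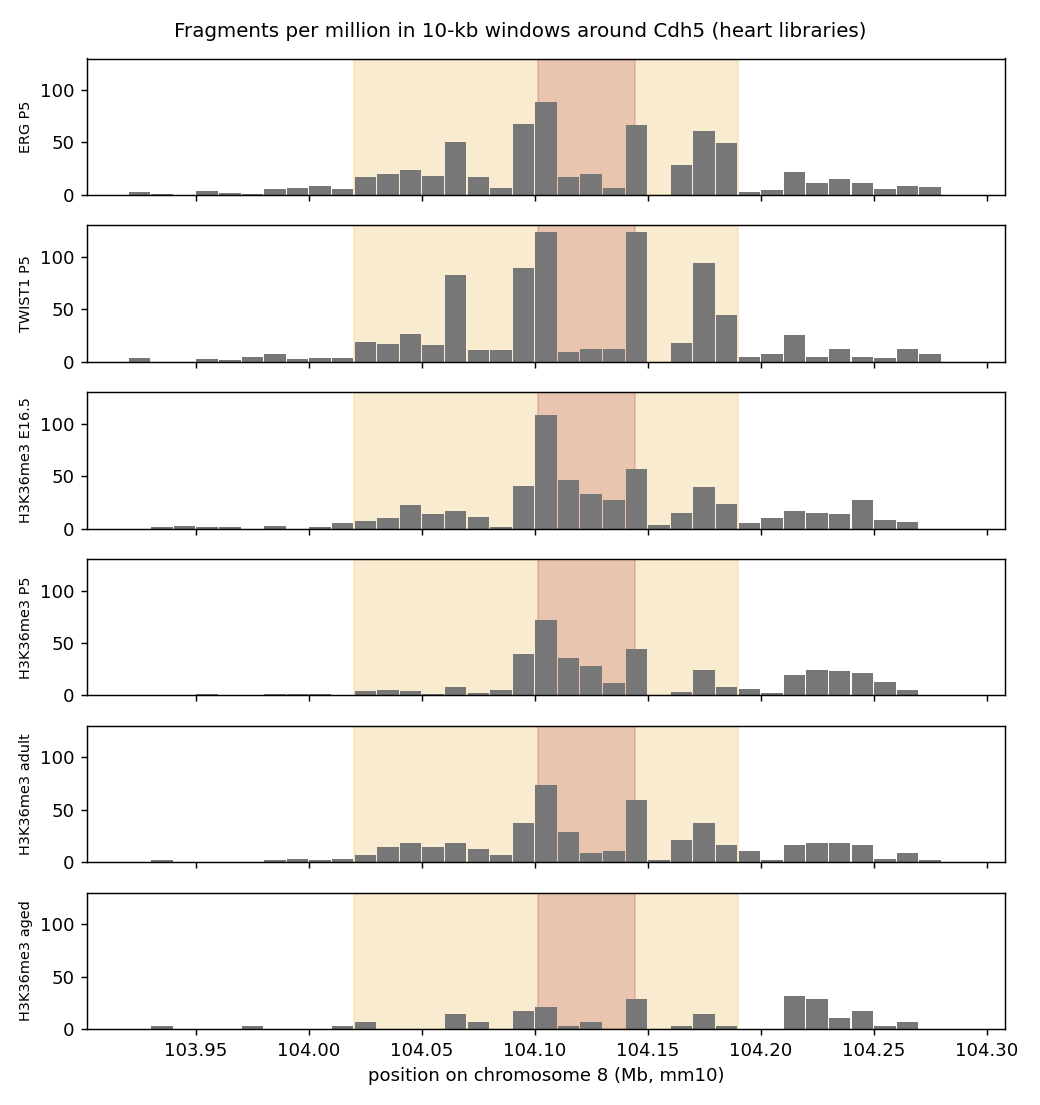
Fragments scaled to library size (vertical axis) in windows of 10 kb along chromosome 8 (horizontal axis, Mb) for ERG, TWIST1 and H3K36me3 in heart, with the segment of 170 kb from 104020001 to 104190000 in yellow and the gene Cdh5 in red. Over the segment the density was 8.52 times the genome mean for ERG, 10.8 for TWIST1, 7.29 at E16.5, 4.56 at P5, 5.98 in the adult and 1.96 in the aged heart.

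Clustering the 1384 H3K36me3 cells with at least 1000 fragments gave 7 clusters, and 6 when the genes of every list were left out. A simulated population with no structure gave 12, so the number of clusters says nothing about the number of cell types. Membership depends on depth and settings: against the 7 clusters of all genes, the adjusted Rand index was 0.300 with cells thinned to 1000 fragments, and 0.567 to 0.655 for the other settings tried. In the clustering without list genes, an endothelial-like cluster of 473 cells was led by Adgrf5, Nfib, Tcf4, the VEGF receptor Kdr and Kitl, and had an endothelial level 2.08 (1.99 to 2.17) times that of the other cells. It held 54.3% (48.3 to 60.2) of E16.5 cells, 63.9% (59.3 to 68.4) of P5 cells, 17.5% (12.6 to 23.4) of adult heart cells and 0 of 104 aged heart cells, which allows up to 3.48%. Within the first and the second set of lanes it held 65.3% and 31.1% of E16.5, 81.2% and 44.0% of P5, and 21.3% and 13.3% of adult heart cells. Its 473 cells came as 341 from the first set, 132 from the second and 0 from the set of the aged organs, so the absence of aged heart cells cannot be told apart from the set of lanes. Another cluster of the same clustering, led by the blood cell genes Cyth4, Arhgap45, Rac2, Bin2 and Myo1g, had a myeloid level 1.87 (1.71 to 2.05) times that of the others. It held 3.40% of adult heart cells, 36.5% (27.3 to 46.6) of aged heart, 38.6% of brain, 65.3% of kidney, 56.0% of liver and 71.9% of lung cells. Of its 236 cells, 225 lay in the set of lanes of the aged organs. That set also held 116, 93 and 18 cells of other clusters, so the set alone does not define this cluster. The set may still contribute, and the cluster is left unnamed. No doublet caller was run.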

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

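The values in this part come from fragments outside the comparisons, looked at after the main results were known, and no explanation was tested for them.

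Among groups with more than 3 of them, mitochondrial fragments numbered 1855 at E16.5, 2496 at P5, 1212 in the adult heart, 8 in the aged heart, 7 in aged liver, 4 for ERG and 2410 for TWIST1. They made up 0.227%, 0.191% and 0.219% of the fragments of the E16.5, P5 and adult heart, 0.00284% of the aged heart, and 0.287% of the TWIST1 fragments against 0.000367% of the ERG fragments. The share differed between sets of lanes: it was 0.327% in the first and 0.0434% in the second at E16.5, 0.305% and 0.0675% at P5, and 0.322% and 0.109% in the adult heart. The 3 TWIST1 sets had 0.167%, 1.01% and 0.00300%. Chromosome Y held 2051 fragments over all groups. Contigs outside the main chromosomes held 5229, of which 3346 lay on a single unplaced contig.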

How the results depend on the processing

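The settings by set of lanes, whole gene bodies and the ribosomal DNA segment were chosen after the data were seen, as was the choice of lists treated here as main answers. No paired analysis was possible because the labels give no replicate numbers across groups and no test was run, but E16.5, P5 and the adult heart were also compared within each set of lanes. Of 5937 alternative values of 732 results, 5444 stayed within the interval of the reported value, 481 moved outside it otherwise and 12, in 10 results, changed the sign of a value whose interval did not hold 0; 237 of those that moved are percentiles among random lists matched on gene length too. The cause was not tested for any value below. The planned motif alternatives were not run.

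With the scaling by the median ratio, the aged against adult matrix median was -0.88. Without 2 kb at both gene ends, the cell cycle median at P5 against E16.5 was 0.014, the endothelial median in adult against P5 -0.76 and oxidative phosphorylation in brain 0.0072. In cells with at least 1000 fragments, the aged against adult endothelial median was -0.33. With equal weight per cell, the adult against P5 endothelial median was -0.42 and the kidney endothelial median in kidney 0.31. In odd-numbered cells, the endothelial median in heart was -0.049, and in brain the brain endothelial, oxidative phosphorylation and NF-kB medians were -0.038, 0.23 and 0.011. In even-numbered cells, cardiomyocyte and kidney epithelial medians in adult against P5 were 1.32 and -0.52, the latter over 2 members. With the density between genes subtracted, adult against P5 gave 1.62 for cardiomyocyte, 1.28 for neural and -1.27 for cell cycle genes, and aged against adult -0.88 for matrix genes. The first 2 values say little, since 8 of 19 and 6 of 12 members lay at 0 in at least 1 group, and both were 1.43 before members at 0 in both groups were left out, a choice made after the values were seen. With 50 fragments per member, the aged against adult myeloid median was -0.051. With thinned groups, the aged against adult cell cycle median was 0.22, the brain endothelial median in brain -0.16 and the log2 of Pald1 -0.089.

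In the first set of lanes, the endothelial median at P5 against E16.5 was 0.36 and the kidney endothelial median in adult against P5 -0.066. In the second, the cell cycle median at P5 against E16.5 was 0.42, and in adult against P5 the fetal growth and matrix medians were 0.029 and -0.18. The ERG share near gene ends was 8.57% with 500-bp and 18.1% with 2-kb windows, 10.9% in cells with at least 1000 fragments, 13.0% and 12.6% in odd- and even-numbered cells, and 23.2%, 8.62%, 12.9% and 13.0% by set of lanes. The TWIST1 share was 10.4%, 21.6%, 14.3%, 15.1% and 16.0% in the same order, 15.7% without the ribosomal DNA segment, and 15.1%, 17.8% and 14.8% by set of lanes. Over whole gene bodies the log2 of Olfr524 was -0.38, the value that equal fragment counts of both factors give. The cluster with the highest myeloid level held 33.7% of aged and 4.37% of adult heart cells in a clustering of all genes; changing a second choice there, it held 26.9% of aged and 0% of adult heart cells with 15 components, and 25% of aged heart cells with thinned cells. Resolution 0.5 gave 4 clusters.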

Other observations

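Apart from the test of neural genes with the density between genes subtracted, the tests in this part were chosen after the results were seen.

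The ribosomal DNA segment on chromosome 17 held a larger share of H3K36me3 fragments in adult and aged than in young libraries: 0.0919% (0.0854 to 0.0987) at E16.5, 0.0616% (0.0574 to 0.0660) at P5, 0.239% (0.226 to 0.252) in the adult heart, 0.172% (0.158 to 0.189) in the aged heart and 0.255% (0.238 to 0.272) in aged brain. Among immune genes, Nlrc5, an activator of MHC class I genes, stood in the adult heart at 3.61 (2.37 to 5.61) times its P5 level, while the interferon and antigen presentation list as a whole had a median of -0.05. In the aged heart, the adhesion molecule Icam1 stood at 1.88 (1.24 to 2.86) times and Ciita, an activator of MHC class II genes, at 1.88 (1.06 to 3.34) times the adult level. Their lists were not detectably different there, with medians of 0.05 (-0.25 to 0.55) for NF-kB and adhesion and 0.16 (-0.04 to 0.70) for interferon and antigen presentation genes.

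Some cells shared many fragments with identical positions. Of 8235711 pairs of cells, 383 pairs (531 cells) shared at least 20 such fragments and 104 pairs (173 cells) at least 50. All 383 pairs lay within the same group and set of lanes, and the highest share was 61.2% of the shallower cell's fragments. Counting such positions once per set of lanes was among the alternatives.

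Myeloid genes were higher in the aged than the adult heart, and if leukocytes among the profiled cells were the source, cells of the cluster led by blood cell genes should carry far more myeloid and far less endothelial signal than the other aged heart cells. Their myeloid level was 2.13 (1.55 to 2.95) times and their endothelial level 0.767 (0.603 to 0.969) times that of the others, between the bounds set for either answer, with lymphocyte genes at 0.613 (0.403 to 0.912) and neural genes at 0.357 (0.256 to 0.490) times, though the cluster was itself picked for its myeloid level. In other groups the same cluster stood apart less or the other way, with a myeloid level of 0.335 (0.0906 to 0.867) times that of the rest over 7 adult heart cells, 1.33 (1.06 to 1.68) in brain, 1.41 (0.912 to 2.25) in kidney, 1.23 (1.0 to 1.51) in liver and 1.21 (0.706 to 2.22) in lung. More untargeted fragments in the aged library would raise neural genes as well, and their median was 0.077 (-0.37 to 0.50), an interval that still overlaps the myeloid one. The hepatocyte median was 0.056 (-0.52 to 0.56), while kidney epithelial genes were higher and cardiomyocyte genes lower, as given above. Gene bodies held 73.6% of aged and 70.4% of adult heart fragments, the reverse of what more untargeted fragments alone would give. These values point both ways. With 0 sets of lanes holding both groups, leukocytes, untargeted fragments, sets of lanes and age itself cannot be told apart.

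Genes of heart muscle, neurons and 3 more cell types weighed here were higher in the adult than the P5 heart. The data argue against the sets of lanes as the whole cause for neural genes (0.79, 0.32 to 1.17, in the second set and 1.10 in the first) and cardiomyocyte genes (0.99, 0.75 to 1.44, and 1.17), but leave them open for hepatocyte (1.0, -0.05 to 1.47, in the second set), myeloid (0.56, -0.07 to 0.95) and kidney epithelial genes (1.20 over 1 member, and 0.35, -0.17 to 1.11, in the first set). Set over the fragments between genes, neural, cardiomyocyte and kidney epithelial genes stood at 1.52 (1.36 to 1.69), 1.79 (1.63 to 1.96) and 1.35 (1.09 to 1.67) times the P5 value. Hepatocyte genes, at 1.26 (0.996 to 1.59), and myeloid genes, at 1.03 (0.899 to 1.17), had intervals that held 1. These ratios cannot decide on untargeted fragments. DNA between genes also held the mark, with H3K36me3 at 21.5 (17.1 to 26.6) times its mean near Eng. More untargeted fragments could therefore raise genes without the mark by more than the fragments between genes. In P5, 6 neural and 8 cardiomyocyte members lay at or below the density between genes. A test fixed earlier, the neural median after subtraction of the density between genes, gave 1.28 (0.87 to 1.60) over 7 members but is void, because 6 of 12 members lay at or below that density in at least 1 group; its treatment of members at 0 was set after the values were seen, and before that it gave 1.43. Heart muscle chromatin may contribute to cardiomyocyte genes (1.07, against 0.82 for hepatocyte genes) and cannot be excluded for neural genes (1.03, 0.74 to 1.24), all intervals overlapping. Untargeted fragments and the stage itself stay open for all of these lists. In the clustering without list genes, a cluster not described above held 19.9% of adult, 0.673% of P5 and 9.29% of E16.5 heart cells. Another held 36.4%, 2.02% and 7.86%. Whether the higher lists come from such a subset of adult cells stays open as well.

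The segment of 170 kb around Cdh5, the gene that marks the lineage, was dense in the heart libraries, including its DNA between genes. Within 80 kb of Cdh5, ERG and TWIST1 fragments between genes were 9.97 (9.09 to 10.9) times the genome's mean between genes, from 474 fragments. Near Eng, the highest other endothelial gene, the value was 7.93 (5.74 to 10.7), from only 43 fragments over 11788 bp. Egfl7 followed at 4.76 and Mmrn2 at 3.53, and the other genes of the list were lower. Regulatory activity may account for the dense segment, though only the interval of Eng reached that of Cdh5. Extra copies of the segment in the profiled cells may do so too, since H3K36me3 there was 8.98 (8.0 to 10) times the mean; Eng reached 21.5 (17.1 to 26.6), which met a first bound against extra copies, but active genes raise H3K36me3 nearby, so that bound was replaced after the value was seen. The share of fragments between genes that fell in the segment was lower in the aged than the adult heart, at 0.334 (0.166 to 0.616) times, as fewer copies would give, but also as lower endothelial activity or another set of lanes would. The labels used here do not state a transgene, and these explanations cannot be told apart.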
